A study of Homo sapiens with 12 samples.

How the data were processed

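RNA of the human melanoma line WM35 was measured on 12 arrays in 5 groups: the control with 2 arrays, each drug at 8 h with 3 and each drug at 24 h with 2. Per the labels' protocols, cells were plated overnight and given ciclopirox, crizotinib or DMSO, and total RNA was amplified, biotin-labelled and hybridized to Illumina arrays. The labels give no time for the controls and do not say whether arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. All arrays lay on 1 slide, so that position on the slide and group cannot be told apart.

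The authors deposited a scanner table and a table of normalized values. Per the file headers, the scanner table gives an intensity per probe and array and a detection p-value for 47230 probes. Per the submitters' processing notes GenomeStudio was used, with a version not given in the sources used here. Between 27.1% and 30.2% of the deposited intensity values lie below 0, so background had been subtracted. The deposited table of normalized values holds a linear intensity for 38223 of these probes, from 12.1 to 31794, with column medians of 25.0 to 26.4. How the authors normalized it, beyond near-equal quantiles, is not given in the sources used here, and its log2 was taken here.

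The analysis had been planned on the scanner values after background correction and quantile normalization with neqc, each array being linked to its sample by the array code in the sample description. When the tables were compared, the log2 values of each normalized column followed exactly 1 scanner column at r = 0.997 to 0.998, with r of at most 0.994 for any other. For 10 of the 12 samples that scanner column was not the one the description names. Deviations of arrays from the overall mean correlated within groups at 0.29 on average under the column headings of the normalized table and at 0.11 under the description codes. Among 100000 random assignments of the arrays the 95th percentile was 0.044, and the shares as high were 1e-05, the smallest they can give, and 0.00735. The 2 links have 4 of 9 within-group pairs in common, so the share for the description codes does not speak for them. With only the 10 treated arrays reassigned, the shares were 0.00012 and 0.029. After this comparison, and before any test between groups, the log2 values of the normalized table under its own headings were made the main values. The planned setting is reported as an alternative. This is a departure from the plan made after array identities and replicate agreement had been seen, and which link is right was not settled by any label. For detection calls and further normalizations, scanner arrays were linked through the normalized columns whose values they follow, a link chosen after seeing the data.

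Probes were named through a table of the platform's annotation, which gave 1 gene for 27004 probes, several for 4 and none for 11215 of the normalized table. Gene identifiers were looked up in the RefSeq table of GRCh38.p14, where 26970 were found, and no coordinates are given because the arrays' build is not stated. Probes with a detection p under 0.05 on at least 2 arrays were kept (20491 in the normalized table). The probe with the highest mean stood for a gene, which left 12034 genes, 2938 of them with 2 or more probes past the filter. Another probe of a gene was called the other way for CCDC50, HNRNPDL and SNHG7 at 24 h of ciclopirox against the control and for BEX1, CRYZL1 and DUT at 24 h of crizotinib. Between 8 h and 24 h this held for CCDC50, DUT, HNRNPDL, IMPDH1, SLC6A15 and SNHG7 under ciclopirox and for DUT, NRP2, SNHG7 and SPIN2B under crizotinib. It also held for SH3KBP1 and SPIN2B between the drugs at 24 h and for SPIN2B in the interaction. TFRC, CA9 and EGLN3, which had been chosen beforehand, have no named probe here and were not analysed here. A further gene of that choice is not reported.

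Differences were tested two-sided with lmFit and eBayes of limma 3.58.1 in R 4.3.3, in 1 fit of all 12 arrays with 1 coefficient per group, so that groups of 2 and 3 arrays share 1 estimate of the spread with 7 residual degrees of freedom. Adjusted p is by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Fold changes are differences of mean log2 intensity, given with their SE where stated, and the median SE was 0.143 against the control at 8 h and 0.157 at 24 h. A gene not detected at p under 0.05 on any array of the dimmer group has only a bound. It is given as at least N-fold, the mean of the brighter group against the mean of, per array, the higher of the gene's own value and the lowest value among probes detected at p under 0.01. The 9 comparisons were each drug and time against the control, 24 h against 8 h per drug, the drugs against each other at each time, and the drug by time interaction.

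Before the data were examined, 28 gene lists were fixed: HIF targets, glycolytic enzymes, iron handling, iron and 2-oxoglutarate oxygenases, DNA replication, mitosis, p53 targets, ATF4 and amino acid response, unfolded protein response, heat shock, ERK output, sterol biosynthesis, lysosome and autophagy, melanocyte pigment, dedifferentiated melanoma, NRF2 targets, NF-kB and cytokines, interferon response, oxidative phosphorylation, ribosome biogenesis, polyamines and eIF5A, metal-responsive genes, BCL2 family, crizotinib target kinases and ligands, and markers of fibroblasts, keratinocytes, endothelium and leukocytes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the arrays. A pair of p-values beside a list gives both in that order. The named genes followed a rule set at the same time. It took the 10 largest rises and 10 largest falls against the control, or 6 of each in other comparisons, among called genes whose arrays do not overlap (not required for the interaction). It added up to 5 called members of each list described and, in every comparison, the genes of a fixed set of 15 that were measured and are reported. HK2 at 24 h of ciclopirox against the control was added after the results were seen. Data were simulated for 12034 genes, with 200 genes changed in 1 group and independent normal noise at the fitted spread. There the fit for ciclopirox at 8 h against the control recovered 56.7% of genes changed 1.5-fold, 95.5% at 2-fold and 100% at 4-fold, with 7 false calls. For ciclopirox at 24 h it recovered 40.3%, 80.6% and 100%, with 6 false calls. These shares belong to that setting and need not hold for the arrays, where the number of changed genes and the noise may differ.

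Correlations between responses were set beside 100 simulations of unchanged groups against the same controls. Alternatives were the description link, other background corrections and normalizations, no filter or a stricter filter on dim probes, the mean of a gene's probes, single probes, 1 control array per drug (added after the data were seen), only the groups compared, eBayes with trend and robust settings, array weights, the replicate number as a block, and leaving out each array. Probes outside the normalized table entered no main comparison.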

Results

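Gene expression was measured in WM35, a human melanoma cell line, with 12 Illumina bead arrays that were labelled as 5 groups. The control group, given the solvent DMSO, held 2 arrays. Ciclopirox, an antifungal compound that binds iron, was represented by 3 arrays at 8 h and 2 arrays at 24 h. Crizotinib, an inhibitor of the kinases MET, ALK and ROS1, was likewise represented by 3 arrays at 8 h and 2 at 24 h. Each drug was given at the concentration that inhibited the cells by 75% in a 72 h assay, and the study set out to derive signatures of both drugs for comparison with patient outcome. The titles of the control arrays give no time, so every comparison with the control may also hold a difference in time in culture. Between 40.5% and 43.3% of the 47230 probes were detected on an array, arrays of 1 group correlated at 0.992 to 0.995 across genes, and 12034 genes were tested. The small number of arrays limits the precision of every value.

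The deposited tables do not name the same array for the same sample. The table of normalized values and the table of scanner values hold the same 12 arrays, but 10 of the 12, all of the treated ones, are given to another sample in the second table, and the 2 controls are the same in both. The arrays headed ciclopirox 24 h replicate 2 and crizotinib 8 h replicates 2 and 3 in the normalized table keep their group under both links. The other treated arrays change group. The values below follow the column headings of the normalized table. Under the array codes of the sample descriptions, limma with Benjamini-Hochberg adjustment called 371 genes for ciclopirox at 8 h against the control and 530 for ciclopirox against crizotinib at 8 h, and 0 in the other 7 comparisons. In those 7 comparisons 589 to 1693 genes had an unadjusted p under 0.05. Of 83 list results recomputed under those codes, 20 had the other direction, and 8 of the 20 passed an adjusted p of 0.05 in that direction (camera, preset correlation). Another 19 kept their direction but lost their call. Every direction and count given here therefore rests on those headings.

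**Figure D1:**
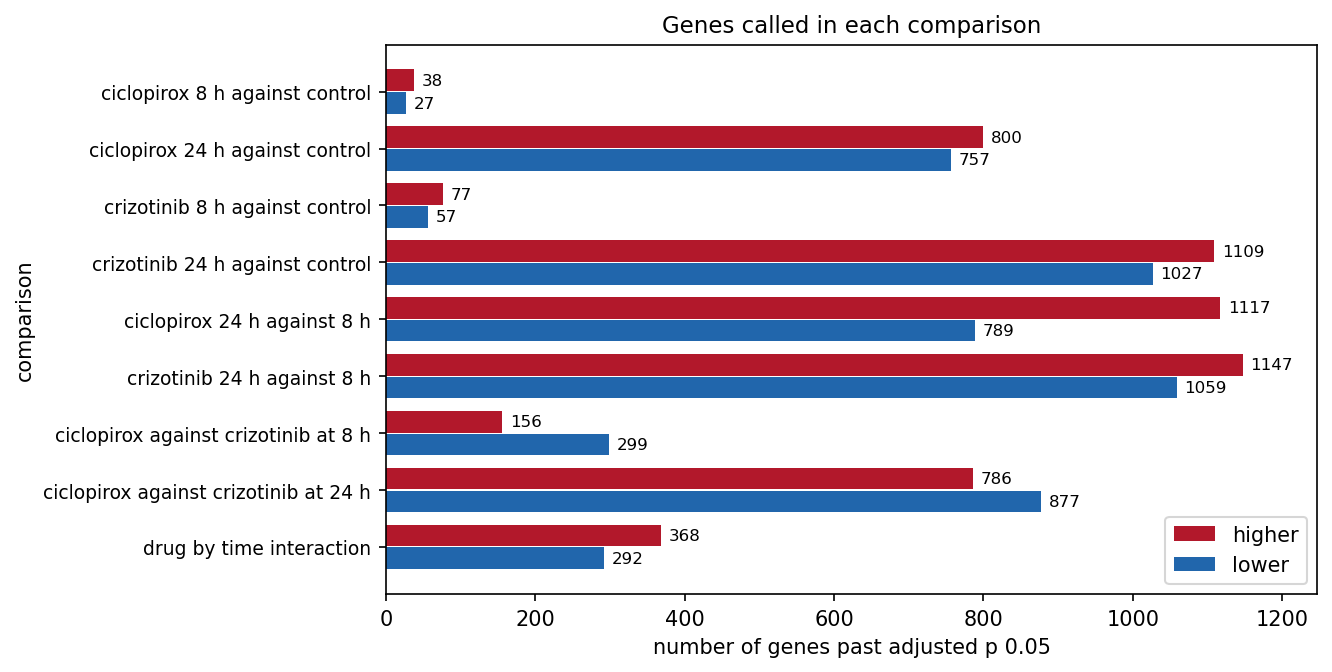
Number of genes past an adjusted p of 0.05 in each of the 9 comparisons, with genes that were higher (red) and lower (blue) in the first-named group or time. Against the control, the bars reach 38 and 27 genes for ciclopirox at 8 h and 1109 and 1027 genes for crizotinib at 24 h.

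After 8 h of ciclopirox, genes that are switched on in low oxygen were higher than in the control. Of 30 measured targets of HIF, the transcription factor of the low-oxygen response, 7 rose and 0 fell, and 18 rose when adjusted over the list alone. The median target was 0.51 higher on the log2 scale (camera, adjusted p = 2.2e-19, and 0.0023 with an estimated correlation). The very low density lipoprotein receptor gene VLDLR rose by 1.01 ± 0.16 (log2, SE, 3 arrays against 2), the mitophagy gene BNIP3 by 0.97 ± 0.14, the mTORC1 inhibitor gene DDIT4 by 0.93 ± 0.11, the transcriptional repressor gene BHLHE40 by 0.92 ± 0.10 and the hexokinase gene HK2 by 0.86 ± 0.14. VEGFA, which encodes a blood vessel growth factor, was 0.66 ± 0.18 higher and NDRG1 0.27 ± 0.09 higher, with adjusted p of 0.15 and 0.26 (limma, Benjamini-Hochberg).

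In all, 65 genes differed between ciclopirox at 8 h and the control, 38 higher and 27 lower, and 11 of them by at least 2-fold. The ubiquitin ligase gene HECW2 had the largest rise (1.57 ± 0.16). Apart from the HIF targets given above, ADAMTS6 (1.31), GLIPR1 (1.07), the actin-binding gene TAGLN (1.06), the potassium channel gene KCNH1 (1.03) and WWC1 (0.99) came next. They were followed by the endothelin gene EDN1 (0.97) and SPRY1 (0.93), which encodes an inhibitor of receptor tyrosine kinase signalling. The largest falls were those of SHISA2 (-1.55 ± 0.15), ART3 (-1.10), the collagen gene COL8A1 (-1.04), the retinol-pathway gene DHRS3 (-1.03), SIPA1L2 (-1.02), the neuregulin receptor gene ERBB3 (-0.97), TRIM51 (-0.96), MXD3 (-0.92), AMACR (-0.88) and the interferon-induced IFIT1 (-0.85). Among 23 genes that respond to ERK signalling, SPRY1, MYC (0.62) and the cyclin gene CCND1 (0.57) rose, and the list as a whole had an adjusted p of 0.108. Of 33 genes of the ATF4 and amino acid response, only DDIT4, which also stood on the HIF list, rose (11 when adjusted over the list alone), with a median of 0.20 and camera adjusted p = 7.3e-10 (adjusted p = 0.068 with an estimated correlation). Of 15 glycolytic enzymes, the aldolase gene ALDOC (0.73) rose, with a camera adjusted p of 0.019 (adjusted p = 0.25 with an estimated correlation). The heat shock list had a median of -0.20 and 0 of 16 genes called, with an adjusted p of 0.0135 (adjusted p = 0.25 with an estimated correlation). ASNS (0.36), HMGCS1 (0.26), MET (0.10), RRM2 (0.08), CDKN1A (0.06), DDIT3 (0.03), MITF (0.00) and DUSP6 (-0.13) did not pass the test, and CDKN1A was not detected in either group. The count was 5 without control replicate 2, 0 without control replicate 1 (1037 genes at an unadjusted p under 0.05 by limma), and 2 when only these 2 groups entered the fit. Under median scaling 25.2% of the called genes were higher, against 58.5% here.

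After 24 h of ciclopirox, the stress response driven by the transcription factor ATF4 had risen across nearly its whole list. Of 33 measured genes, 28 rose and 0 fell (31 when adjusted over the list alone), with a median of 1.08 (camera, adjusted p = 2.5e-30, and 0.0030 with an estimated correlation). The stress-induced genes SESN2 (2.74 ± 0.22), ATF3 (2.66 ± 0.12) and DDIT3 (2.40 ± 0.10) rose most, with CTH, an enzyme of cysteine synthesis (2.28), PPP1R15A, which helps restore translation (1.76), and the asparagine synthetase gene ASNS (1.74 ± 0.11). Targets of p53 rose as well, 16 of 24 (21 when adjusted over the list alone), with a median of 1.10 (camera, adjusted p = 5.1e-20, and 0.0030 with an estimated correlation). SESN2 stood on this list as well as on the ATF4 list. The stress cytokine gene GDF15 had the largest rise of any gene called, 4.58 ± 0.18, and GADD45A (1.97), TP53INP1 (1.83) and SESN1 (1.64) also rose. CDKN1A, which encodes the cell cycle inhibitor p21, was not detected in the control and was at least 2.66-fold higher (adjusted p = 0.00055).

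Cell division genes fell in the same arrays. Of 38 mitosis genes, 32 fell (36 when adjusted over the list alone), with a median of -0.63 (camera, adjusted p = 1.1e-22, and 0.016 with an estimated correlation), among them the cyclin gene CCNB1 (-1.31 ± 0.13), KIF20A (-1.29) and the proliferation marker gene MKI67 (-1.15). Of 38 DNA replication genes, 13 fell (19 when adjusted over the list alone), with a camera adjusted p of 1.2e-08 (adjusted p = 0.057 with an estimated correlation), and the examples were E2F2 (-1.45), POLE2 (-0.76) and MCM6 (-0.69). RRM2, a subunit of the iron-dependent ribonucleotide reductase, was 0.16 ± 0.16 higher and was not called (adjusted p = 0.57). Heat shock genes fell, 11 of 16, with a median of -0.74 (camera, adjusted p = 1.1e-11, and 0.0053 with an estimated correlation). HSPA1A (-2.99 ± 0.25) and HSPA1B (-2.30 ± 0.11) fell most, and their transcripts are near-identical, so the probes may share signal, while the chaperone genes HSPE1 (-1.09) and HSPA8 (-0.86) also fell.

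At 24 h of ciclopirox 9 of 30 HIF targets were higher than in the control and 0 lower (12 and 1 when adjusted over the list alone), with a median of 0.29 (camera, adjusted p = 6.7e-05, and 0.034 with an estimated correlation). The hormone gene STC2 (1.61), VEGFA (1.48 ± 0.20), DDIT4 (1.46), VLDLR (1.17) and BHLHE40 (0.94) were higher, and so was NDRG1 (0.72), and of these STC2 and DDIT4 also stood on the ATF4 list. HK2 was 0.23 ± 0.15 higher and was not called (adjusted p = 0.36). Of 23 ERK output genes, 10 rose and 0 fell, with a median of 0.36 (camera, adjusted p = 1.2e-08, and 0.016 with an estimated correlation), led by the immediate early genes FOS (1.80) and EGR1 (1.63) and the phosphatase gene DUSP5 (1.20). Of 21 genes of the unfolded protein response, 4 rose, including XBP1 (1.42) and DNAJB9 (0.94), and the list had an adjusted p of 0.731. In the sterol list 4 of 20 genes fell and 1 rose (adjusted p = 0.081), with HMGCS1 at -0.52 ± 0.11. In the lysosome and autophagy list 3 of 32 rose and 2 fell (adjusted p = 0.221), with the autophagy genes WIPI1 (1.42) and MAP1LC3B (0.87) among those that rose.

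Altogether 1557 genes differed between ciclopirox at 24 h and the control, 800 higher and 757 lower, 211 of them by at least 2-fold. Further large rises were those of HECW2 (2.44), the thioredoxin-binding gene TXNIP (2.42), the glycine transporter gene SLC6A9 (2.34), the kinase gene RPS6KA2 (2.26) and the interleukin 33 receptor gene IL1RL1, which was not detected in the control and was at least 3.58-fold higher. Besides the heat shock genes, the largest falls were those of the chemokine gene CCL2 (-2.20), COL8A1 (-1.94), RPPH1, the RNA of RNase P (-1.77 ± 0.44), DKK3 (-1.70), TRIM51 (-1.68), the receptor gene FGFR3 (-1.62), MIX23 (-1.54) and ROPN1 (-1.52). MYC (0.79) and MET (0.50) rose, while DUSP6 (0.24) and the melanocyte regulator gene MITF (-0.14) were not called. The count was 667 without control replicate 2, 715 without control replicate 1 and 572 with only these 2 groups in the fit.

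**Figure D2:**
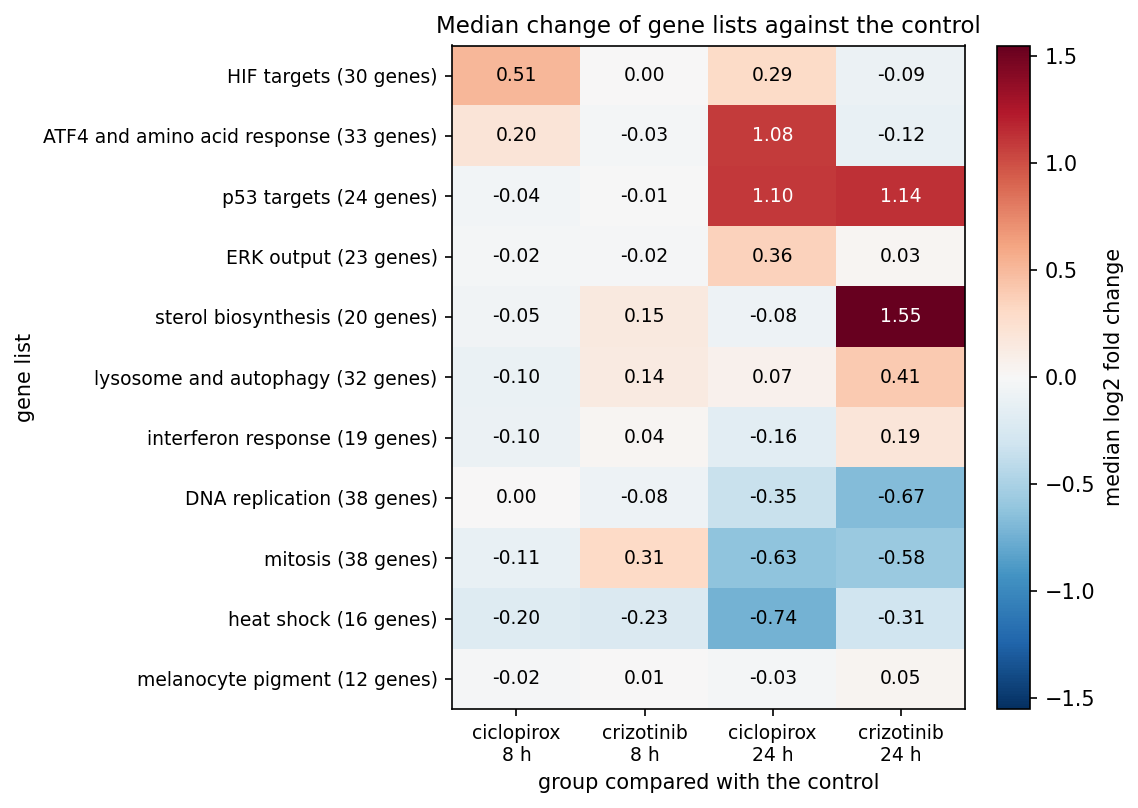
Median log2 fold change against the control of 11 gene lists (rows, with the number of measured genes) in the 4 treated groups (columns), where red is higher and blue lower. The ATF4 list stands at 1.08 for ciclopirox and -0.12 for crizotinib at 24 h, and the sterol list at -0.08 and 1.55.

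After 8 h of crizotinib, genes of cholesterol synthesis were higher than in the control. Of 20 measured sterol genes, 7 rose and 0 fell (9 when adjusted over the list alone), with a median of 0.15 (camera, adjusted p = 8.7e-07, and 0.048 with an estimated correlation). INSIG1, a sterol sensor of the endoplasmic reticulum, rose by 1.81 ± 0.13 (3 arrays against 2), and the enzyme genes HMGCS1 by 1.79 ± 0.10, MSMO1 by 1.64 ± 0.11, MVK by 1.08 and SQLE by 1.06. Of 32 lysosome and autophagy genes, 4 rose (8 when adjusted over the list alone), which were the autophagy receptor gene SQSTM1 (0.79), FNIP1 (0.71), RRAGC (0.53) and RRAGD (0.50), with a median of 0.14 (camera, adjusted p = 9.0e-07, and 0.048 with an estimated correlation). Of 38 mitosis genes, 6 rose (17 when adjusted over the list alone), among them AURKA (0.66), CDC25C (0.64) and CENPA (0.62), with a median of 0.31 (camera, adjusted p = 8.9e-15, and 0.048 with an estimated correlation).

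In all, 134 genes differed between crizotinib at 8 h and the control, 77 higher and 57 lower, 28 by at least 2-fold. Other rises were those of the cytokine gene IL24 (1.69), TXNIP (1.66), SH2D5 (1.44), KCNH1 (1.34), the phosphatidate phosphatase gene LPIN1 (1.30), SLCO4A1-AS1 (1.17) and the cyclin gene CCNA1 (1.16). The largest falls included 3 genes of hyaluronan turnover, the synthases HAS3 (-1.59 ± 0.13) and HAS2 (-1.17) and the hyaluronan-degrading CEMIP (-1.51), which form no list fixed beforehand. The neutrophil chemokine gene CXCL8 fell (-1.47), and so did the Notch ligand gene JAG1 (-1.23), SHISA2 (-1.22), the cholesterol exporter gene ABCA1 (-1.17), BET1L (-1.15), PMEPA1 (-1.08) and FZD8 (-1.05). HAS2 and ABCA1 were each detected on only 1 of the 3 crizotinib arrays, so the sizes of their falls are uncertain. Of 11 genes of the NF-kB and cytokine list, CXCL8, IL1B (-0.99) and IL1A (-0.79) fell and 0 rose, with an adjusted p of 0.327 for the list. In the HIF list the 1 gene called was PFKFB3 (-0.60), with an adjusted p of 0.495 for the list. The heat shock list had a median of -0.23 with 1 of 16 genes called, HSPA1B (-0.56) (camera, adjusted p = 1.5e-05, and 0.048 with an estimated correlation).

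Among ERK output genes 2 of 23 rose, one of them MYC (0.63), and the list had an adjusted p of 0.671. DUSP6, a feedback phosphatase of ERK, was -0.39 ± 0.10 from the control and did not pass (adjusted p = 0.11). NDRG1 (0.31), DDIT3 (0.31), CDKN1A (0.13), RRM2 (0.08), MITF (0.04), MET (0.04), VEGFA (-0.05) and ASNS (-0.14) were not called either, and CDKN1A was not detected in either group. The count was 29 without control replicate 1, 35 without control replicate 2 and 29 with only these 2 groups in the fit. Under median scaling 22.3% of the called genes were higher, against 57.5% here.

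At 24 h of crizotinib the sterol genes had risen further above the control. Of 20 genes 13 rose and 0 fell, with a median of 1.55 (camera, adjusted p = 5.5e-16, and 0.0060 with an estimated correlation), and HMGCS1 was 3.65 ± 0.11 higher (log2, SE, 2 arrays against 2), MSMO1 3.56, INSIG1 2.83, SQLE 2.55 and DHCR7 2.31. Lysosome and autophagy genes rose in 17 of 32 cases and 1 fell (23 and 1 when adjusted over the list alone), with a median of 0.41 (camera, adjusted p = 5.1e-11, and 0.0071 with an estimated correlation). Examples were WIPI1 (1.99), the lysosomal glycoprotein gene GPNMB (1.78), SQSTM1 (1.31), the cholesterol transporter gene NPC1 (1.28) and the sialidase gene NEU1 (1.26). CD68, a lysosomal membrane gene that stood on the list of leukocyte markers, rose by 1.11, and that list had an adjusted p of 0.298.

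Targets of p53 rose in 20 of 24 cases, with a median of 1.14 (camera, adjusted p = 6.6e-19, and 0.0060 with an estimated correlation). GDF15 rose by 3.81 ± 0.18, TP53INP1 by 2.59, SESN1 by 2.37, ZMAT3 by 2.11 and the pro-apoptotic gene BAX by 1.18. CDKN1A was not detected in the control and was at least 5.40-fold higher. DNA replication genes fell in 32 of 38 cases, with a median of -0.67 (camera, adjusted p = 1.8e-20, and 0.0086 with an estimated correlation), including E2F2 (-1.72), RRM2 (-1.25 ± 0.16), MCM10 (-1.23) and DTL (-1.22). Mitosis genes fell in 28 of 38 cases, with a median of -0.58 (camera, adjusted p = 3.4e-18, and 0.024 with an estimated correlation), including CDCA3 (-1.06) and CCNA2 (-0.98).

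The ATF4 list at 24 h of crizotinib held 4 genes that rose and 6 that fell, with an adjusted p of 0.347. ATF3 (1.29) and DDIT3 (1.15) rose and ASNS fell (-0.44). In the unfolded protein response 7 of 21 genes fell and 2 rose (camera, adjusted p = 0.037, and adjusted p = 0.191 with an estimated correlation), with the chaperone genes HSPA5 (-1.11) and HYOU1 (-0.95) among the falls. In the heat shock list 6 of 16 fell and 1 rose (camera, adjusted p = 0.00045, and adjusted p = 0.063 with an estimated correlation), with HSPA1A at -1.29 and HSPE1 at -0.69. The HIF list was split, with 11 genes that rose, such as BHLHE40 (1.73), and 5 that fell (adjusted p = 0.668), and its median of -0.09 and mean of 0.08 differ in sign. VEGFA was -0.56 ± 0.20 from the control (adjusted p = 0.076), and NDRG1 rose by 0.61.

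Altogether 2136 genes differed between crizotinib at 24 h and the control, 1109 higher and 1027 lower, 326 of them by at least 2-fold. The largest rise was that of IL24 (4.19 ± 0.15), and other large rises were those of the neuropeptide receptor gene NPFFR2 (3.05), the smooth muscle actin gene ACTA2 (2.98), SH2D5 (2.67) and the phosphatase gene PTPRR, which was not detected in the control and was at least 5.93-fold higher. COL8A1 (-2.16), RPPH1 (-2.10 ± 0.44), the serine protease inhibitor gene SERPINA3 (-2.06), the small nucleolar RNA SNORD3D (-1.80), EDN1 (-1.70), MIX23 (-1.59), CNIH2 (-1.59), NUDT1 (-1.52) and GPRIN1 (-1.48) fell most beside E2F2. MET itself rose by 0.33 ± 0.10 (adjusted p = 0.043), and MYC (0.19), MITF (-0.05) and DUSP6 (-0.20) were not called. The count was 1062 without control replicate 1, 1159 without control replicate 2 and 1136 with only these 2 groups in the fit.

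**Figure D3:**
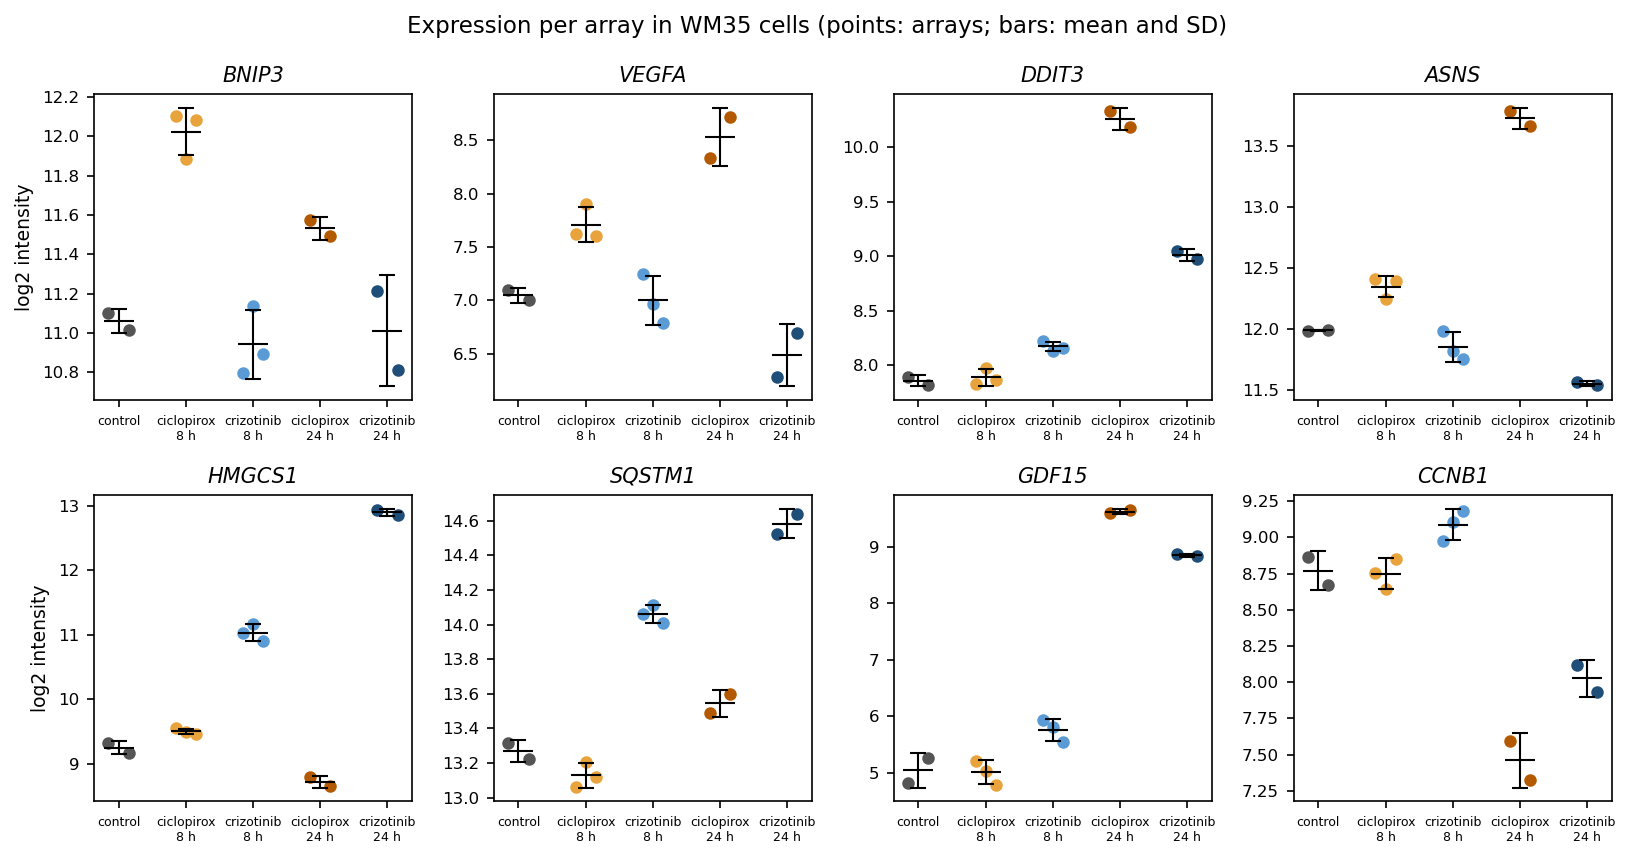
Log2 intensity of 8 genes on each of the 12 arrays (points), with the mean and SD of each group (black). DDIT3 and ASNS stand highest at 24 h of ciclopirox, HMGCS1 and SQSTM1 at 24 h of crizotinib, and CCNB1 is lower at 24 h than in the control under both drugs.

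Between 8 h and 24 h of ciclopirox, p53 targets rose in 19 of 24 cases (camera, adjusted p = 5.0e-20, and 0.0059 with an estimated correlation) and ATF4 genes in 26 of 33 (adjusted p = 2.6e-22, and 0.0062). Mitosis genes fell in 25 of 38 cases (adjusted p = 9.7e-20, and 0.024) and heat shock genes in 11 of 16 (adjusted p = 5.0e-10, and 0.0086). HIF targets went both ways, with 5 of 30 that rose and 7 that fell, such as PFKFB4 (-1.05 ± 0.16) and HK2 (-0.63 ± 0.14), and a median of -0.12 (adjusted p = 0.24, and 0.45 with an estimated correlation). The largest rises were those of GDF15 (4.61 ± 0.16), the epithelial gene SPRR2D (2.43), IL24 (2.40), SESN2 (2.37), DDIT3 (2.37) and ATF3 (2.20). The largest falls were those of HSPA1A (-2.21), ANKRD1 (-1.87), RPPH1 (-1.85), HSPA1B (-1.78), CCL2 (-1.76) and FGFR3 (-1.64). ASNS (1.38), VEGFA (0.82), NDRG1 (0.45), MET (0.40) and DUSP6 (0.38) rose, HMGCS1 fell (-0.78), and CDKN1A, not detected at 8 h, was at least 2.36-fold higher. MYC (0.17), RRM2 (0.07) and MITF (-0.14) were not called. In all 1906 genes differed, 1117 higher and 789 lower, and 162 by at least 2-fold, with 866 called without the first 24 h array, 1189 without the second and 983 with only these 2 groups in the fit.

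Between 8 h and 24 h of crizotinib, sterol genes rose in 14 of 20 cases (camera, adjusted p = 3.1e-15, and 0.0070 with an estimated correlation) and p53 targets in 20 of 24 (adjusted p = 1.7e-20, and 0.0055). Mitosis genes fell in 36 of 38 cases, with a median of -0.94 (adjusted p = 3.2e-29, and 0.010), and DNA replication genes in 28 of 38 (adjusted p = 2.8e-18, and 0.013). GDF15 (3.09 ± 0.16), ACTA2 (2.93), SUGCT (2.63), IL1B (2.55) and IL24 (2.50) rose most, and CDKN1A was at least 4.76-fold higher. TMEFF2 (-1.84), SERPINA3 (-1.76), COL8A1 (-1.61), LHX4 (-1.55), CNIH2 (-1.44) and the nuclear lamina gene LMNB1 (-1.41) fell most. HMGCS1 (1.86), DDIT3 (0.84) and MET (0.29) rose, RRM2 (-1.33) and MYC (-0.44) fell, and NDRG1 (0.30), DUSP6 (0.19), MITF (-0.09), ASNS (-0.30) and VEGFA (-0.51) were not called. In all 2206 genes differed, 1147 higher and 1059 lower, and 269 by at least 2-fold, with 1131 called without the first 24 h array and 1433 with only these 2 groups in the fit.

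Set against each other at 8 h, ciclopirox had higher HIF targets and crizotinib higher sterol, lysosomal and mitosis genes. Of 30 HIF targets 15 were higher under ciclopirox and 0 lower (median 0.44; camera, adjusted p = 1.6e-19, and 0.0024 with an estimated correlation). Lower under ciclopirox were 19 of 38 mitosis genes (adjusted p = 1.5e-20, and 0.021), 9 of 20 sterol genes (adjusted p = 7.1e-09, and 0.021) and 9 of 32 lysosome and autophagy genes (adjusted p = 9.8e-12, and 0.0083). EDN1 (1.80 ± 0.14), VLDLR (1.66), XYLT1 (1.63), CXCL8 (1.28), HECW2 (1.24) and ADAMTS6 (1.18) were higher under ciclopirox, as were VEGFA (0.71) and ASNS (0.50). IL24 (-2.09 ± 0.12), SLCO4A1-AS1 (-2.04), INSIG1 (-1.74), GAS2L3 (-1.54), HMGCS1 (-1.53) and MSMO1 (-1.52) were lower. DUSP6 (0.26), MET (0.06), RRM2 (0.00), MYC (-0.01), NDRG1 (-0.04), MITF (-0.04), CDKN1A (-0.07) and DDIT3 (-0.28) were not called, and CDKN1A was not detected under either drug. In all 455 genes differed, 156 higher and 299 lower under ciclopirox, 33 by at least 2-fold, with 221 called without crizotinib replicate 1 and 239 with only these 2 groups in the fit.

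At 24 h the drugs differed most in the ATF4 and sterol lists. Of 33 ATF4 genes 31 were higher under ciclopirox and 0 lower (median 1.05; camera, adjusted p = 7.0e-34, and 0.0027 with an estimated correlation), and of 20 sterol genes 15 were lower and 0 higher (median -1.38; adjusted p = 3.9e-20, and 0.0027). Lower under ciclopirox were also 16 of 32 lysosome and autophagy genes (adjusted p = 4.4e-10, and 0.0088), 8 of 19 interferon response genes (adjusted p = 4.3e-05, and 0.031) and 7 of 16 heat shock genes (adjusted p = 1.2e-05, and 0.031). DNA replication genes were higher in 13 of 38 cases (adjusted p = 1.1e-08, and adjusted p = 0.063 with an estimated correlation). SLC6A9 (3.41 ± 0.29), EDN1 (2.95), SESN2 (2.28), the interleukin 18 receptor gene IL18R1 (2.25) and SERPINA3 (2.22) were higher under ciclopirox, as were ASNS (2.17), VEGFA (2.04), RRM2 (1.40), DDIT3 (1.25), MYC (0.60) and DUSP6 (0.45). IL1RL1 was at least 2.59-fold higher. HMGCS1 (-4.17 ± 0.11), MSMO1 (-3.46), DHCR7 (-3.09), INSIG1 (-2.91), MVD (-2.64) and CDKN1A (-1.02) were lower, and FGFBP1 was at least 4.44-fold lower. MET (0.17), NDRG1 (0.11) and MITF (-0.09) were not called. In all 1663 genes differed, 786 higher and 877 lower under ciclopirox, 305 by at least 2-fold, with 913 called without crizotinib replicate 1 and 659 with only these 2 groups in the fit.

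The change from 8 h to 24 h differed between the drugs for 660 genes, 368 with a more positive change under ciclopirox and 292 under crizotinib, 229 by at least 2-fold. Leaving out any 1 array gave 277 to 495, with 277 without the first crizotinib array at 24 h. ATF4 genes changed more positively under ciclopirox in 27 of 33 cases (median 1.01; camera, adjusted p = 4.3e-27, and 0.0035 with an estimated correlation). Sterol genes changed more positively under crizotinib in 13 of 20 cases (median -0.87; adjusted p = 1.4e-18, and 0.0035). TXNIP rose by 1.92 between the times under ciclopirox and changed by -0.07 under crizotinib, a difference of 1.99 ± 0.18 (adjusted p = 0.00032). HMGCS1 changed by -0.78 under ciclopirox and by 1.86 under crizotinib, a difference of -2.64 ± 0.15 (adjusted p = 3.4e-05). NDRG1 (0.16), DUSP6 (0.19), MET (0.11) and MITF (-0.05) showed no called difference.

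The responses to the 2 drugs at 24 h overlapped. Genes higher than the control under both numbered 324, against 73.7 for independent lists of the same lengths, and genes lower under both 370, against 64.6. Their fold changes correlated at 0.50 across 12034 genes, which are not independent replicates, and unchanged groups set against the same 2 controls gave 0.50 in simulation. The covariance was 0.079 against a simulated 0.017. At 8 h, 7 genes were higher and 7 lower under both drugs, against 0.243 and 0.128 for independent lists, with a correlation of 0.48 (simulated 0.60) and a covariance of 0.027 (simulated 0.017). With 1 control array for each drug, an alternative added after the data were seen, the correlation at 24 h was 0.38 or 0.35 and the covariance 0.065 or 0.062, depending on which drug took which control. Genes higher under both then numbered 121 or 127 (17.1 or 21.0 for independent lists), and genes lower under both 107 or 109 (12.1 or 13.4). At 8 h the correlation was then 0.15 both ways and the covariance 0.011, and too few genes were called against 1 control for an overlap to be counted. Part of the excess of shared genes over independent lists at 8 h may come from the shared controls. The covariance at 8 h was 0.0097 above that of the simulation, which already held the same 2 controls. The time of either control is not given.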

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

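The list tests on time in culture given below were chosen after the results were seen, and the comparison of the drugs' time courses had been planned.

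The change from 8 h to 24 h differed between ciclopirox and crizotinib for 660 genes by limma with Benjamini-Hochberg adjustment, and for 277 to 495 when any 1 array was left out. More positive under ciclopirox were the changes of SLC6A9 (2.88 ± 0.38), TXNIP (1.99), SESN2 (1.98), SPRR2D (1.97), VLDLR-AS1 (1.86), GRK6 (1.80), ASNS (1.68), DDIT3 (1.53), RRM2 (1.40), VEGFA (1.33) and MYC (0.61). More positive under crizotinib were those of MVD (-2.71 ± 0.29), HMGCS1 (-2.64), DHCR7 (-2.40), ACAT2 (-2.27), the prostaglandin synthase gene PTGES (-2.19) and NPFFR2 (-2.02). CDKN1A was not detected in either group at 8 h, so its called difference of -0.95 starts from values below detection and is not an exact size. SLC6A9 rose by 1.62 under ciclopirox and changed by -1.26 under crizotinib, and MVD changed by -0.66 and 2.05. RRM2 changed by 0.07 under ciclopirox and fell by 1.33 under crizotinib.

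Among lists, the ATF4 genes had a median difference of 1.01, the sterol genes -0.87 and the heat shock genes -0.47, with camera adjusted p of 0.0035, 0.0035 and 0.019 with an estimated correlation. The preset correlation also called the following lists, which were lost with an estimated correlation: mitosis 0.35 (adjusted p = 0.176), DNA replication 0.27 (adjusted p = 0.213), ERK output 0.19 (adjusted p = 0.222), lysosome and autophagy -0.10 (adjusted p = 0.222), HIF targets -0.18 (adjusted p = 0.176), NRF2 targets -0.23 (adjusted p = 0.299) and interferon response -0.27 (adjusted p = 0.145).

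Of 3566 detected probes that the normalized table leaves out, 162 were called for crizotinib at 24 h against the control, 102 higher and 60 lower, and 94 for ciclopirox at 24 h, 18 for crizotinib at 8 h and 3 for ciclopirox at 8 h. These values are scanner values after neqc, linked through the normalized columns, so their processing differs from the main one. Of the 12034 genes tested in the main setting, 17.7% were called for crizotinib and 12.9% for ciclopirox at 24 h. At 8 h these shares were 1.1% and 0.54%. The largest rise at 24 h of crizotinib among the probes left out was 3.75, and the control has no stated time.

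Whether the rises of lists at 24 h came from time in culture alone was weighed through the interaction, since both drugs were sampled at both times. If time alone moved a list, its genes should change alike under both drugs. The SE of a median given here was taken over the genes of a list as if they were independent. It does not measure the spread between arrays. The median interaction was 1.01 for the ATF4 genes (SE of the median 0.111) and -0.87 for the sterol genes (0.258). Both had a camera adjusted p of 0.0035 with an estimated correlation, which is hard to square with time in culture alone as the source of either rise. For p53 targets the median was -0.26 (0.193, camera adjusted p = 0.497 with an estimated correlation), which does not decide the question for the list. A count of members, used for this list alone, gave 10 of 24 that differed when adjusted over the list alone (7 to 11 without any 1 array). Among 22 members detected in every treated group and not on the ATF4 list, 8 differed when adjusted over those alone. Of the 10, 4 were more positive under ciclopirox, such as GDF15 (1.52 ± 0.23), and 6 under crizotinib, such as TP53I3 (-1.17 ± 0.14) and TIGAR (-0.90 ± 0.21). The changes of those members are hard to square with time in culture alone, judged by a spread between arrays that may be technical. Because those members went both ways, they do not show that a drug added to the rise of the list as a whole. Time in culture may be a part of that rise, as of the others. These values rest on the column headings of the normalized table.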

How the results depend on the processing

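Whether the replicate numbers pair samples was not settled. Residuals of same-numbered arrays of different groups correlated at -0.21 to 0.28 (21 pairs, median 0.02), and other numbers had a median of -0.0043. Residuals of a group sum to 0, so those of a group of 2 arrays mirror each other, and these pairs are not independent. Of 12 arrays, 8 correlated best with one of their own number. Mirrored arrays do not enter that count independently, and no chance value was worked out for it. With the replicate number as a block, 28 genes were called for ciclopirox at 8 h against the control (42.9% of them higher, against 58.5% without the block), 60 for crizotinib at 8 h and 376 for the interaction. Of the values recomputed with the block, 30 of 322 for genes and 2 of 83 for lists lost their call. The settings through scanner values linked by the normalized columns, and 1 control array per drug for the correlation of responses, were chosen after seeing the data, and the others were planned. Gene and list values were recomputed for those the text could name, a choice made after reversals under the description link had been seen. The cause was not tested for any of the changes given here.

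Under the planned setting, scanner values with neqc and the array codes of the sample descriptions, limma called 371 genes for ciclopirox at 8 h against the control, 7 of them also called by the main setting in the same direction. It called 530 between the drugs at 8 h (54.7% of them higher under ciclopirox, against 34.3%), 17 in the same and 23 in the opposite direction. It called 0 for ciclopirox at 24 h (1119 at an unadjusted p under 0.05), crizotinib at 8 h (665) and crizotinib at 24 h (678) against the control. It also called 0 for 24 h against 8 h of ciclopirox (1693) and of crizotinib (589), for the drugs at 24 h (1067) and for the interaction (822). Of the values recomputed, 51 of 322 for genes and 39 of 83 for lists kept their call or lack of a call under it. In 189 gene values and 19 list values the direction stayed but the call was lost, and 2 and 5 gained a call. The remaining 80 for genes and 20 for lists had the other direction under it, with a call in at least one of the 2 settings. Of these, 2 genes and 8 lists passed an adjusted p of 0.05 in the other direction (limma for genes, camera at the preset correlation for lists), and for 1 gene and 7 lists the main setting had passed as well. That p is given beside each of them, and the rest did not pass. For ciclopirox at 8 h against the control the gene values were TAGLN -0.090, VLDLR -0.0078, EDN1 -0.58, HK2 -0.32, CCND1 -0.026. For ciclopirox at 24 h against the control the value of HMGCS1 was 0.57. For crizotinib at 24 h against the control the gene values were IL24 -0.42, ACTA2 -0.086, TP53INP1 -0.043, RPPH1 0.14, SERPINA3 0.39, E2F2 0.11, EDN1 0.94, MIX23 0.21, FTL -0.17, RRM2 0.12, MCM10 0.13, DTL 0.0026. Further genes there were CDKN1A -3.4e-04, SESN1 -0.26, ZMAT3 -0.33, HSPA5 0.13, SQSTM1 -0.086, NPC1 -0.18, NEU1 -0.27, CCN2 0.59, JUN 0.61, THBS1 0.53, IL1B -0.24, IFIT2 -0.063. Further genes there were IFIT3 -0.028, BAX -0.15, CD68 -0.0020, ASNS 0.36. The list medians there were sterol biosynthesis -0.0015, lysosome and autophagy -0.074, p53 targets -0.030, DNA replication 0.0099, ATF4 and amino acid response 0.28 (adjusted p = 0.039), interferon response -0.050, NRF2 targets -0.059, ribosome biogenesis 0.16 (adjusted p = 0.00094). For 24 h against 8 h of ciclopirox the gene values were GDF15 -1.23, IL24 -1.67, SESN2 -0.044, DDIT3 -0.26, ATF3 -0.40, HSPA1A 0.13, ANKRD1 0.74, RPPH1 1.18, FGFR3 0.36, NDRG1 -0.046, CDKN1A -1.35, HK2 0.20. The list medians there were p53 targets -0.61 (adjusted p = 1.9e-09), mitosis 0.43 (adjusted p = 6.4e-08). For 24 h against 8 h of crizotinib the gene values were GDF15 -0.57, ACTA2 -0.071, SUGCT -0.036, IL24 -1.44, CDKN1A -0.046, SERPINA3 0.32, CNIH2 0.012, RRM2 0.027, DDIT3 -0.16, HMGCS1 -1.06, MYC 0.035. The list medians there were p53 targets -0.043, sterol biosynthesis -0.16, DNA replication 0.072. For the drugs at 8 h the gene values were EDN1 -0.40, VLDLR -0.16, XYLT1 -0.62, ADAMTS6 -0.26, IL24 2.36 (adjusted p = 0.042), SLCO4A1-AS1 1.0011, INSIG1 0.58, HMGCS1 0.98, MSMO1 1.26, VEGFA -0.086, CDKN1A 2.30 (adjusted p = 0.019). The list medians there were sterol biosynthesis 0.67 (adjusted p = 0.00065), lysosome and autophagy 0.25 (adjusted p = 0.0002). For the drugs at 24 h the gene values were EDN1 -0.78, IL18R1 -0.023, SERPINA3 -0.52, HMGCS1 0.33, MSMO1 0.52, INSIG1 0.77, FGFBP1 0.36, RRM2 -0.057, CDKN1A 0.9999. The list medians there were sterol biosynthesis 0.12, lysosome and autophagy 0.16 (adjusted p = 0.00029), interferon response 0.032, DNA replication -0.19 (adjusted p = 1.4e-05). For the interaction the gene values were SESN2 -0.51, DDIT3 -0.100, GDF15 -0.66. The list median there was ERK output -0.18.

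With only the compared groups in the fit, the counts were 2 for ciclopirox at 8 h (100% higher), 572 for ciclopirox at 24 h, 29 for crizotinib at 8 h and 1136 for crizotinib at 24 h against the control. They were 983 and 1433 for 24 h against 8 h of ciclopirox and crizotinib, and 239 and 659 for the drugs at 8 h and 24 h. Of the values recomputed in this way, 61 of 322 for genes and 3 of 83 for lists lost their call. Against the control at 8 h, eBayes with trend and robust called 177 genes for ciclopirox and 296 for crizotinib, array weights 147 and 220, and no filter on dim probes 38 and 78. Trend and robust called 1014 for the interaction, and no filter 361, with 269 for the drugs at 8 h. Scanner values linked through the normalized columns gave, for ciclopirox and crizotinib at 8 h against the control, 160 and 258 with no background correction and 201 and 331 with normexp and an offset of 50. For the interaction these gave 1027 and 1073, and the offset gave 690 for the drugs at 8 h. Cyclic loess gave 114 and median scaling 111 for ciclopirox at 8 h. Under median scaling the share of called genes that were higher was 25.2% for ciclopirox and 22.3% for crizotinib at 8 h against the control (58.5% and 57.5% in the main setting). It was 80.1% and 75.6% for 24 h against 8 h of ciclopirox and crizotinib (58.6% and 52.0%) and 48.1% for the drugs at 8 h (34.3%). The median of all genes was then -0.10 for crizotinib at 8 h.

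Leaving out 1 array at a time gave, for ciclopirox at 8 h against the control 0 to 66 (0 without control replicate 1, 5 without control replicate 2, 36 without ciclopirox 8 h replicate 1, 23 without ciclopirox 8 h replicate 2, 26 without ciclopirox 8 h replicate 3). It gave, for ciclopirox at 24 h against the control 667 to 1592 (715 without control replicate 1, 667 without control replicate 2, 836 without ciclopirox 24 h replicate 1). It gave, for crizotinib at 8 h against the control 29 to 128 (29 without control replicate 1, 35 without control replicate 2, 60 without crizotinib 8 h replicate 1, 66 without crizotinib 8 h replicate 2, 78 without crizotinib 8 h replicate 3). It gave, for crizotinib at 24 h against the control 1062 to 2139 (1062 without control replicate 1, 1159 without control replicate 2, 1307 without crizotinib 24 h replicate 1). It gave, for 24 h against 8 h of ciclopirox 866 to 1887 (866 without ciclopirox 24 h replicate 1, 1189 without ciclopirox 24 h replicate 2). It gave, for 24 h against 8 h of crizotinib 1131 to 2210 (1131 without crizotinib 24 h replicate 1). It gave, for the drugs at 8 h 221 to 429 (236 without ciclopirox 8 h replicate 1, 247 without ciclopirox 8 h replicate 2, 229 without ciclopirox 8 h replicate 3, 221 without crizotinib 8 h replicate 1, 278 without crizotinib 8 h replicate 2, 233 without crizotinib 8 h replicate 3). It gave, for the drugs at 24 h 913 to 1614 (966 without ciclopirox 24 h replicate 1, 1063 without ciclopirox 24 h replicate 2, 913 without crizotinib 24 h replicate 1, 1067 without crizotinib 24 h replicate 2). It gave, for the interaction 277 to 495 (418 without ciclopirox 8 h replicate 1, 381 without ciclopirox 8 h replicate 3, 325 without ciclopirox 24 h replicate 1, 370 without ciclopirox 24 h replicate 2, 405 without crizotinib 8 h replicate 1, 277 without crizotinib 24 h replicate 1, 402 without crizotinib 24 h replicate 2). For ciclopirox at 8 h the 0 came with 1037 genes at an unadjusted p under 0.05 in limma, and 20% of the 5 genes called without control replicate 2 were higher.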

Other observations

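The interleukin genes IL1A and IL1B rose at 24 h under both drugs. Against the control, whose time is not given, they rose by 1.31 and 1.25 under ciclopirox and by 1.43 and 1.55 under crizotinib (limma, Benjamini-Hochberg). In the NF-kB and cytokine list 4 of 11 genes rose and 1 fell, the chemokine gene CCL2, under ciclopirox (median 0.47; camera, adjusted p = 0.034, and adjusted p = 0.117 with an estimated correlation). Under crizotinib 4 rose and 2 fell (adjusted p = 0.069). Interferon response genes rose in 5 of 19 cases at 24 h of crizotinib, including IFIT2 (1.10), the antigen transporter gene TAP1 (0.76) and IFIT3 (0.75), with a camera adjusted p of 0.037 (adjusted p = 0.191 with an estimated correlation). Under ciclopirox 2 of 19 fell, among them IFIT1 (-1.32), with an adjusted p of 0.081. In the BCL2 family 4 of 12 genes rose at 24 h of ciclopirox, such as the pro-apoptotic HRK (1.69) and PMAIP1 (0.90) (adjusted p = 0.117), and 2 of 12 at 24 h of crizotinib, HRK (1.37) and BAX (1.18) (adjusted p = 0.964).

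Of 17 genes of dedifferentiated melanoma cells, 4 rose at 24 h of ciclopirox, among them the receptor gene EGFR (0.88), the matrix gene TNC (0.75) and CCN1 (0.68), and WNT5A fell (-0.91), with a camera adjusted p of 0.047 (adjusted p = 0.250 with an estimated correlation). At 24 h of crizotinib 6 fell, such as CCN2 (-1.28), JUN (-1.03), THBS1 (-0.97) and TNC (-0.84), and the integrin gene ITGA3 rose (0.71) (adjusted p = 0.224). Ribosome biogenesis genes fell in 5 of 24 cases at 24 h of crizotinib, with a camera adjusted p of 0.00083 (adjusted p = 0.212 with an estimated correlation). NRF2 targets rose in 5 of 18 cases there, with FTL (0.70) among them, and 1 fell (adjusted p = 0.037, and adjusted p = 0.410 with an estimated correlation). Iron handling genes rose in 4 of 13 cases at 24 h of crizotinib and 1 fell (adjusted p = 0.068). Of the iron and 2-oxoglutarate oxygenases, 2 of 24 rose and 4 fell at 24 h of crizotinib (adjusted p = 0.344). The results of both lists under ciclopirox are not given here. The lists of glycolytic enzymes (adjusted p = 0.489), melanocyte pigment (0.806), oxidative phosphorylation (0.990), polyamines and eIF5A (0.806), metal-responsive genes (0.701) and crizotinib target kinases and ligands (0.163) did not pass at 24 h of crizotinib. Nor did markers of fibroblasts (0.347, with LUM called at 0.69) and endothelium (0.625), and keratinocyte markers, with 2 genes measured, were not tested.

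The measure of replicate agreement used next was set after the conflict between the tables was seen, while the HIF comparison and the splits were set before their results were seen. The 2 deposited tables give 10 of the 12 arrays to different samples. The links share 4 of their 9 within-group pairs of arrays, and if the description codes were right, the 5 pairs that only they put in 1 group should agree at least as well as the 5 that only the normalized columns do. They correlated at -0.051 on average (-0.23 to 0.14), against 0.27 (0.17 to 0.44), and the 2 ranges do not overlap. With the shared pairs, these means follow from the within-group means of 0.11 and 0.29 that had led to the choice of link, so that they are the same evidence and not a second test. As such they argue against the description codes, but do not show that each column heading is right. If the normalized columns were right, an iron-binding drug may be supposed to raise HIF targets over crizotinib at 8 h, since the hydroxylases that mark HIF for degradation need iron, and the median difference was 0.44 (camera, adjusted p = 1.6e-19), against 0.01 (adjusted p = 0.778) under the description codes. This is consistent with the normalized columns as a hypothesis, which only the submitters' records could settle.

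The difference between the drugs at 8 h was set beside all other splits of the same 6 arrays into 3 and 3. The real split gave 455 genes and the highest other split 0, so that 1 of 10 splits reached the real count. With 10 splits the share could not fall under 0.05 whatever the data, so the comparison could not decide whether the count arose by chance. Every other split also mixes arrays of both drugs, which puts any real difference into the spread within its groups. The 0 is therefore no measure of chance. Nor can such splits tell the drug from position on the slide.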
